A study of Caenorhabditis elegans with 2 samples.

How the data were processed

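The series measured binding of SKN-1, a bZIP-type transcription factor of the oxidative stress response, by ChIP-seq in whole first-stage (L1) larvae of the nematode Caenorhabditis elegans. The worms, of strain OP178, carried an integrated transgene (wgIs178) with eGFP-tagged skn-1 in an unc-119(ed3) background, and the labels name 1 group with 2 biological replicates. Fragments of 150 to 350 bp are given in the labels. There was no second condition, so nothing was compared between groups.

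The authors deposited lists of genomic regions in narrowPeak layout, for the ce10 and the ce11 assembly separately. Per the deposited readme, each replicate's list was made from that replicate's alignments and 1 control alignment shared by both replicates, and a pooled list was made from both replicates together. These lists are the regions and background given to the irreproducible discovery rate (IDR) procedure, and so hold background regions as well as peaks. The authors also deposited an optimal IDR-thresholded list, called optimal peaks here. Each region carries a signal value deposited by the authors, which ranks regions within 1 list and was used here only for that. Each region also carries a −log10 q-value, as deposited, which reached its maximum in 67.3% of the optimal peaks and was therefore not used for ranking. The caller, the aligner, the IDR threshold, the strain of the control and the number of reads are not given in the sources used here, and the control alignment was not analysed here. The depth of each replicate is therefore unknown, and intervals below cover the counting of regions or genes only.

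In ce11, the deposited lists held 3484 optimal peaks, 27729 pooled regions and 30000 regions per replicate. All 3484 optimal peaks were also in the pooled list. Region widths were nearly constant within a list, at 304 bp for 99.7% of replicate 1's regions, 280 bp for 99.7% of replicate 2's and 296 bp for 95.5% of optimal peaks, so width carried no information on the extent of binding. Positions are ce11 coordinates counted from 1. The ce10 lists were used for counts and for overlap within ce10, and no coordinates were converted.

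Genes and transcript starts came from Ensembl release 115 (WBcel235, the same assembly as ce11), with 19973 protein-coding genes on the 6 nuclear chromosomes. A promoter window ran from 1000 bp upstream to 200 bp downstream of each annotated transcript start, and a gene was called bound when an optimal peak summit fell in 1 of its windows. The series holds no ChIP of worms without the tag. Whether a peak was specific to SKN-1 was therefore not tested, and bound means only that a peak lay there. Summits in no promoter window were assigned in order to coding sequence, UTR, intron, another gene type or intergenic sequence. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

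The replicates were compared over the 3484 strongest regions of each list, a region being shared when the summits lay within 100 bp, with 100 random placements along the same chromosomes as the chance level. Shares of promoters, of the X chromosome and of the middle of 3 equal parts of each autosome were tested with two-sided exact binomial tests against the bases covered, and 1000 random placements gave a second chance level for promoters. The 39 gene lists were each tested with a two-sided Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment at 0.05. The 12 motifs were searched within 75 bp of each summit and in an equal window 1000 bp away, moved to the other side where another optimal summit lay within 200 bp of it or the window left the chromosome. An exact McNemar test was applied to the pairs, with adjustment over the 12 motifs, and up to 500 versions of each motif with its positions permuted gave a ranking that holds base composition constant. All 2080 canonical 6-mers were tested likewise at an adjusted p of 0.01. Motif frequency was compared across 5 equal bins of the peaks by signal with 100000 permutations. Other gene types were tested within 200 bp of the summit. Peaks and genes are not independent of one another, since neighbouring genes share promoters and families sit in clusters, so these p-values describe these lists and not the spread between worm cultures. The values given for each replicate's list were computed the same way from its 3484 strongest regions, except where the full list is named. Ranks within a replicate, and the regions counted around skn-1 and at the left end of X, come from its full list of 30000.

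The genes named follow a rule set before the data were examined. It takes up to 4 bound members per gene list with the highest signal, the genes at the 20 strongest optimal peaks, a fixed set of 12 genes (skn-1, wdr-23, gst-4, gcs-1, gst-10, unc-119, med-1, med-2, end-1, end-3, elt-2 and elt-7), every member of the list of reported SKN-1 targets, and the 5 strongest peaks of each replicate with no region of the other replicate within 100 bp. Genes named outside it are said to be so. The symbols glrx-32, cdr-5, numr-2, sqrd-2, daf-21, hsp-16.11, hsp-16.49, atf-5 and rde-3 matched no protein-coding gene name of the annotation and were left out of their lists.

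Because reads cannot be placed uniquely in repeated sequence, the share of 30-base words found once in the genome was computed for every promoter window, after the data had been examined. It was below 90% for 3112 genes (15.6%). The aligner's treatment of such reads is not given in the sources used here.

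The tests were checked on simulated data. Over 100 draws on the 19973 genes, 98% of lists made to differ were called and 1.4% of unchanged lists were. These lists were of equal size and of genes drawn at random, so small lists and clustered genes were not covered. The lists made to differ were all bound at the same rate, well above the rest. Smaller differences and lists bound less often were therefore not covered either. Over 50 draws of 3000 window pairs, a planted motif was called in 100% of draws and the other motifs in 0.727%. In 10 draws of 3000 pairs, a planted 6-mer was called in all 10, with 2 other 6-mers called. The motif and the 6-mer were planted at a fixed rate, so the recovery of smaller differences was not covered. Both sets of simulated windows were drawn at random from the genome. The rates of other motifs and 6-mers called therefore do not cover the difference in GC content between real summits and control windows (43.5% and 36.3%). A simulated pair of 3000-region lists with 59.4% planted overlap gave 59.7%. Alternatives tried were the ce10 lists, other summit distances and promoter windows, the 1742 strongest optimal peaks, each replicate's own list, assignment to the nearest gene, other gene backgrounds, a logistic model with upstream distance and GC content, and other motif and control windows.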

Results

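Binding of eGFP-tagged SKN-1 was mapped in L1 larvae from 2 biological replicates, and the question open to the data was where in the genome the factor was found. SKN-1 is the worm counterpart of the mammalian Nrf factors and is known for activating detoxification genes and, in the embryo, for specifying endoderm. In ce11 the 2 replicates together gave 3484 optimal peaks, and the ce10 list held 3434. The files give no read counts, so the depth of each replicate is unknown. Of the ce11 peaks, 601 lay on chromosome I, 552 on II, 608 on III, 519 on IV, 522 on V and 682 on X.

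The replicates placed their strongest regions at largely the same sites. Among the 3484 strongest regions of each, 2256 of replicate 1's summits (64.8%, Wilson 95% interval 63.2 to 66.3) lay within 100 bp of a summit of replicate 2. Random placement of replicate 2's regions gave 0.717% on average and 1.09% at most, and drawing as many regions at random from its full list of 30000, a chance level added after the data were seen, gave 9.79%. Across the shared regions, the signal values of the 2 replicates had a Spearman rho of 0.614, a description across regions that are not independent replicates. Agreement between the replicates' own lists followed strength. With the list split into 5 equal bins by signal, 94.5% (92.6 to 96.0) of replicate 1's strongest bin and 31.6% (28.2 to 35.1) of its weakest were shared. The optimal peaks were selected by the authors for agreement between these replicates, so the next values follow in part from that selection. Among them, 692 of 696 in the strongest bin (99.4%) and 84 of 697 in the weakest lay within 100 bp of the 3484 strongest regions of both replicates. In all, 2271 optimal peaks met that stricter rule, while 95.3% of optimal peaks had a region of replicate 1's full list within 100 bp and 97.2% had one of replicate 2's.

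Regions without a counterpart in the other replicate mostly had one nearby. For 543 of replicate 1's strongest regions and 527 of replicate 2's, the other replicate's full list had no summit within 100 bp, but the nearest one was at a median of 191 bp and 206 bp, respectively. The 5 strongest of these in replicate 1 lay by epn-1, pdk-1, hlh-30, ZK470.4 and unc-1, with the other replicate's nearest summit 105 to 149 bp away. In replicate 2 they lay by pqn-41 (a pair of peaks), C30E1.4 (also a pair, 1 of them absent from the optimal list) and B0491.6, at 118 to 406 bp. They ranked 191 to 334 in replicate 1 and 229 to 408 in replicate 2. Of these, pdk-1 and unc-1 lie between 0.5 and 3 Mb of the X chromosome, a segment where regions were dense as a whole. Density varied within it, with 172 regions of replicate 2's full list in the 500 kb around 1.75 Mb and 320 around 0.75 Mb.

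**Figure D1:**
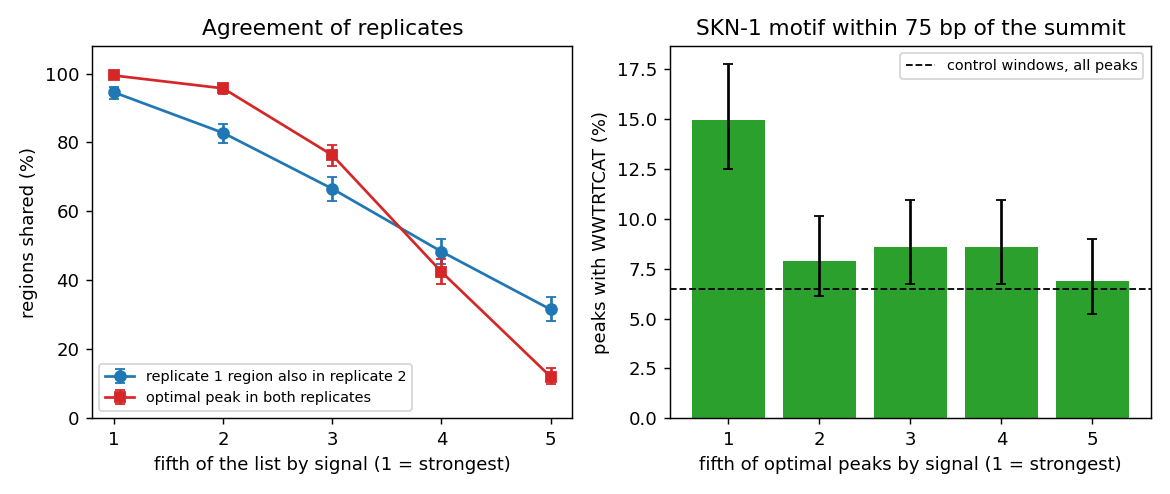
Left, percent of regions shared between replicates in 5 equal bins of the list by signal (1 is the strongest), for replicate 1's 3484 strongest regions found among replicate 2's and for optimal peaks found among the 3484 strongest of both; right, percent of optimal peaks with WWTRTCAT within 75 bp of the summit. Points, bars and whiskers are shares with Wilson 95% intervals, and the dashed line is the 6.47% of control windows; sharing falls from 94.5% to 31.6% for replicate 1, and the motif is at 14.9% in the strongest bin.

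The 3 strongest peaks lay by osgn-1, wdr-23 and cdc-48.1, and 7 of the 20 strongest lay in promoters of proteasome genes. The peak with the highest signal was on chromosome IV, from 4215399 to 4215695, in an intron of osgn-1 (WBGene00017934) 1087 bp upstream of that gene's nearest annotated start. The next was on chromosome I, from 7595468 to 7595844, with its summit 133 bp upstream of wdr-23 (WBGene00008419), which encodes the adaptor that targets SKN-1 for degradation. The third was on chromosome II, from 10563434 to 10563703, 155 bp upstream of cdc-48.1 (WBGene00007352), a p97-type ATPase that delivers ubiquitinated proteins to the proteasome. These 3 peaks had the same ranks, 1, 2 and 3, in each replicate's own list. Among the 20 strongest peaks, 14 were in promoter windows, 4 were intergenic, 1 was in an intron and 1 was in another gene type. Proteasome genes accounted for 7 genes at these peaks, which were rpn-3 (a promoter region shared with hsp-110), rpt-2 (shared with aps-1), rpn-12 (with rad-23), rpn-1 (with ribo-1), rpt-4 (with nfyc-1), rpn-5 (with scc-1) and rpt-1. The remaining peaks among the 20 were those at the promoters of glrx-10, a glutaredoxin, gst-5, a glutathione S-transferase, C02D5.4, tasp-1 with K01G5.10, and ins-39, and those nearest to nhr-84, gtr-1, fbxb-58, D1005.2 and F19G12.9. The last 4 of these and ins-39 lie between 0.5 and 3 Mb of the X chromosome, in the same dense segment.

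Binding was concentrated upstream of genes. Promoter windows held 2299 summits (66%, 64.4 to 67.5), against 26.1% of the genome, a 2.52-fold excess, and none of 1000 random placements exceeded 27.9%. The share was 63.1% in replicate 1 and 65.3% in replicate 2. The median summit lay 195 bp upstream of the nearest protein-coding start, and 80.7% of summits were on the upstream side. Introns held 381 summits (10.9%, against 27.1% of the genome), coding sequence held 25 (0.718% against 19%) and UTRs 28 (0.804% against 2.73%), each below its share of the genome by an exact binomial test (p = 8.15e-122, 2.72e-271 and 5.76e-16). Intergenic sequence held 650 (18.7% against 21.6%, exact p = 1.69e-05), and genes of other types held 101 (2.90% against 3.45%), which did not pass (exact p = 0.0776), nor in replicate 1's list (exact p = 0.329), but did in replicate 2's (2.44%, exact p = 8.10e-04). In all, 3002 of 19973 protein-coding genes (15%) were bound. The 3484 strongest regions of replicate 1 gave 2820 and those of replicate 2 gave 2975.

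Genes reported to depend on SKN-1 were bound more often than other genes. Of 21 reported SKN-1 targets, 14 were bound (66.7% against 15% of other genes, Fisher's exact test, adjusted exact p = 6.63e-07), with 13 in replicate 1 and 14 in replicate 2. Besides wdr-23, gst-5 and gst-7 (rank 58), the bound members were sdz-8 (rank 226), gcs-1, dhs-8, gst-12, gst-4, sod-1, gst-13, nit-1, gsr-1, ugt-13 and gst-30. The peak of gcs-1 (WBGene00001527), the catalytic subunit of glutamate-cysteine ligase, spanned 9038781 to 9039076 of chromosome II, 628 bp upstream of the start, and ranked 308. That of gst-4 (WBGene00001752), widely used as a SKN-1 reporter, spanned 10141970 to 10142265 of chromosome IV, 107 bp upstream, and ranked 573, with rank 2271 in replicate 1 and 249 in replicate 2. The same peak lay in the promoter window of dhs-12, and gst-4 was not bound when each peak went only to its nearest gene. With the narrower promoter window, gcs-1 was not bound. The 7 members not bound were gst-6, gst-14, ctl-1, gst-10, ugt-11, ugt-9 and gst-38. Limits apply to some of them: gst-6, ugt-11, ugt-9 and gst-38 each had a region of the unthresholded pooled list in the promoter window, and only 0% of the promoter of ctl-1 and 14.5% of that of gst-10 is sequence found once in the genome, so that unplaced reads cannot be told from absent binding there.

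Among detoxification families, glutathione S-transferases were the list called more often bound. Of 49 members, 16 were bound (32.7%, adjusted exact p = 0.00409), led by gst-5, gst-7, gst-16 (rank 85) and gst-1 (rank 86). That call was lost against the genes with any pooled region in the promoter (16 of 31 against 33.6%, adjusted exact p = 0.101), and the rates of the families were not compared with one another. The bound members gst-4, gst-5, gst-7, gst-12, gst-13 and gst-30 are also reported SKN-1 targets, so the calls of these lists are not independent. The family was not tested without them. Redox enzymes were bound at 9 of 33 and did not pass (adjusted exact p = 0.132), though the list passed with replicate 2's own regions (10 of 33, adjusted exact p = 0.0414). Its bound members included glrx-10 (rank 14), the methionine sulfoxide reductase msra-1 (rank 51), the peroxiredoxin prdx-2 (rank 271) and gcs-1. Bound counts for lists that did not pass were 8 of 30 short-chain dehydrogenases (dhs-8, dhs-12, dhs-25, in the dense segment of X, and dhs-9 strongest), 8 of 34 ABC transporters (mrp-2, in the dense segment of X, haf-3, haf-7 and pgp-6), 2 of 14 metal response genes (cdr-4 and pcs-1), 3 of 19 genes of sulfur amino acid metabolism (ahcy-1, sams-1 and cysl-2) and 4 of 67 UDP-glucuronosyltransferases (ugt-58, ugt-13, ugt-20 and ugt-64). For the UDP-glucuronosyltransferases, 5 were bound in replicate 1's list and 7 in replicate 2's. Cytochrome P450 genes were bound less often than other genes, at 4 of 74 (cyp-33C6, cyp-33C7, cyp-33C8 and cyp-43A1, adjusted exact p = 0.0387), a call absent from replicate 1's own list (6 of 74, adjusted exact p = 0.236) and from 5 other alternatives, in 3 of which the odds ratio stayed near the 0.322 of the main test (0.305 to 0.375).

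Most proteasome and ribosomal protein genes were bound, that is, had an optimal peak summit in a promoter window. The proteasome list was bound at 30 of 33 members (90.9%, adjusted exact p = 8.00e-21) in the optimal list and in each replicate's, and for 29 of the 30 the promoter peak was in the strongest of the 5 bins by signal. The 3 not bound were rpn-10, pbs-5 and rpn-6.2, named after their values were seen. The strongest were rpn-3 (chromosome III, 8447035 to 8447314, rank 4), rpt-2 (V, 6017684 to 6017934, rank 5), rpn-12 (II, 11652853 to 11653085, rank 8) and rpn-1 (IV, 6910153 to 6910380, rank 9). Ribosomal protein genes were bound at 71 of 79 (89.9%, adjusted exact p = 2.62e-48), with rpl-11.2 (rank 23), rpl-35 (rank 38), rpl-3 (rank 40) and rpl-20 (rank 41) the strongest. The median rank of their strongest peaks was 466, against 65 for proteasome genes. Translation factors were bound at 26 of 37 (adjusted exact p = 4.42e-13), led by eef-1A.1, eef-1A.2, eif-3.C and eef-1G at ranks 57 to 124, with 18 in replicate 1's list and 27 in replicate 2's. With each peak assigned only to its nearest gene, bound counts fell to 23 of 33 proteasome, 41 of 79 ribosomal protein (51.9%) and 18 of 37 translation factor genes, and the calls were kept (adjusted exact p = 1.73e-12, 3.85e-15 and 1.25e-06), so part of the counts above rests on peaks nearer to the start of a neighbouring gene. The gene rpl-11.2 lies in the dense segment of X.

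Mitochondrial, lysosomal and stress genes were also bound more often than other genes. Oxidative phosphorylation genes were bound at 39 of 69 (56.5%, adjusted exact p = 1.83e-14), among them atp-2 (rank 130), asb-2 (rank 199), ndua-8 (rank 205) and cox-6B (rank 218), with 25 of 69 (36.2%) when each peak went only to its nearest gene (adjusted exact p = 3.82e-06). Vacuolar ATPase subunits were bound at 10 of 21 (adjusted exact p = 0.00108), led by vha-15, which lies in the dense segment of X, vha-1, vha-8 and vha-12. The ER unfolded protein response list was bound at 13 of 25 (adjusted exact p = 5.53e-05), with cdc-48.1 and its paralogue cdc-48.2 (rank 123), the BiP-type chaperone hsp-3 (rank 139) and the transcription factor xbp-1 (rank 163). Mitochondrial stress genes were bound at 9 of 13 (adjusted exact p = 5.51e-05), including the import component timm-23 and the chaperones hsp-60, hsp-6 and dnj-10, the first 3 at ranks 263 to 279. Heat shock genes were bound at 10 of 23 (adjusted exact p = 0.00245), with hsp-110 (the peak shared with rpn-3), hsp-90 (rank 153), dnj-13 and sip-1. Autophagy genes were bound at 14 of 27 (adjusted exact p = 3.63e-05), led by the cargo receptor sqst-1 (rank 42) and by lgg-1, lgg-2 and atg-18. Each of these 6 calls held in both replicates' own lists. With each peak assigned only to its nearest gene, ndua-8, cox-6B, vha-1, vha-8, hsp-60, hsp-6 and sip-1 were not bound. With the narrower promoter window, hsp-60 was not bound either.

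Some genes reported upstream of SKN-1 and some bZIP factors were bound. Kinases and other signalling genes reported upstream of SKN-1 were bound at 9 of 20 (adjusted exact p = 0.00307), among them ikke-1 (rank 106), vhp-1, pdhk-2 and rict-1. The 11 not bound, named after their values were seen, were let-363, nekl-2, gsk-3, nsy-1, mpk-1, jnk-1, pmk-1, mlk-1, mek-1, sek-1 and mkk-4. The call was lost with the 1742 strongest optimal peaks (5 of 20), with the narrower promoter window (5 of 20) and against genes with a pooled region (9 of 15 against 33.6%), with adjusted exact p of 0.0546, 0.146 and 0.0993. With those peaks and that window, fewer of the other genes were bound too. The bZIP factor list was bound at 13 of 28 (adjusted exact p = 2.36e-04), led by cebp-1 (rank 22, in the dense segment of X), zip-2 (rank 129), xbp-1 and atf-6 (rank 293). Small RNA machinery was bound at 12 of 28 (adjusted exact p = 0.00104), with rde-4, mut-15, pash-1 and rde-8 the strongest, and this call was lost against genes with a pooled region (adjusted exact p = 0.123). No peak was assigned to skn-1 itself. No pooled region lay between 5629793 and 5692281 of chromosome IV, a stretch of 62488 bp with 14 protein-coding genes, among them skn-1 (5651039 to 5660384), csn-5 and bec-1 (the latter pair named after their positions were seen), so no binding value could be given there. The gene unc-119 had no optimal peak in its promoter window, where the pooled list held 2 weaker regions.

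**Figure D2:**
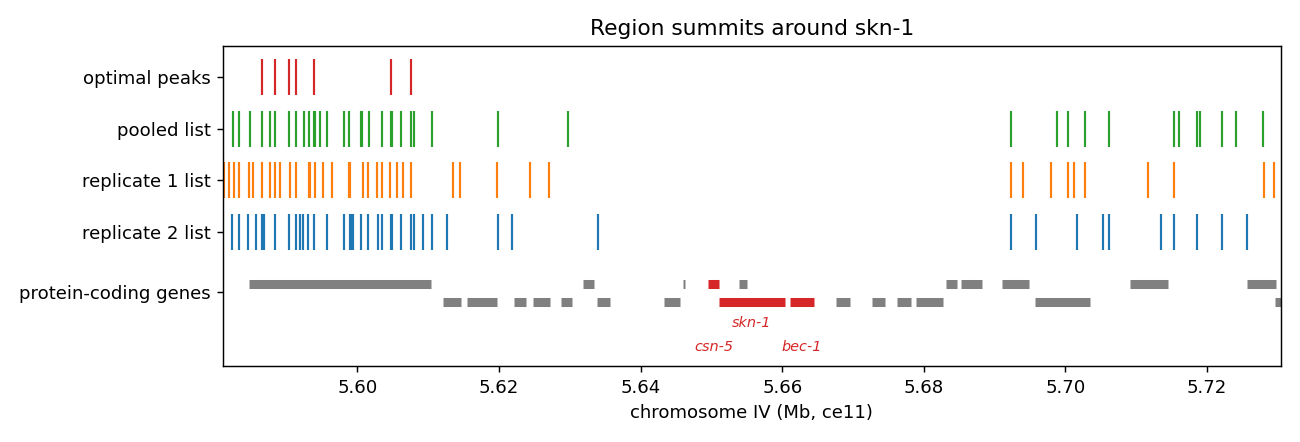
Summits of the optimal peaks, the pooled list and each replicate's full list (vertical ticks) along chromosome IV around skn-1, in Mb of ce11, with protein-coding genes as bars below (upper bars, forward strand; lower bars, reverse strand; skn-1, csn-5 and bec-1 in red). All 4 lists are empty over skn-1, csn-5 and bec-1, with the pooled list's gap 62488 bp long.

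No list of tissue or cell type genes was bound more often than other genes. Of 11 endoderm specification genes, 1 was bound, sys-1, and med-1, med-2, end-1, end-3, elt-2 and elt-7 were not. Of these, elt-7, end-3 and elt-2 had 1 region each of the pooled list in the promoter window. The promoters of med-1 and med-2 are each 85.2% unique sequence, and 3 of the 11 genes are below 90%. Counts for the lists that did not pass were 2 of 38 intestine genes (erm-1 and cpr-4), 2 of 24 pharynx genes (mlc-5, and peb-1 in the dense segment of X), 4 of 32 body wall muscle genes (act-2, act-4, unc-45 and lev-11), 9 of 38 neuron genes (snb-1, syd-2, ric-19 and egl-21 strongest), 0 of 16 genes of the ASI neurons and 3 of 42 germline genes (nos-3, syp-3 and xnd-1). Likewise, 3 of 24 insulin signalling genes (akt-2, daf-18 and pptr-1), 10 of 88 lipid metabolism genes (cpt-2, lbp-9, nhr-49 and acs-2 strongest), 40 of 269 nuclear hormone receptors (nhr-182, nhr-104, nhr-57 and nhr-228) and 5 of 63 homeobox genes (ceh-38, ceh-39 in the dense segment of X, ceh-92 and ceh-100 among them) did not pass. Histone genes were bound at 5 of 72 (his-37, his-35, his-41 and his-24 among them) and did not pass, but 63 of the 72 have promoters with under 90% unique sequence, and among the other 9 the 5 bound genes made a call in the opposite direction (adjusted exact p = 0.0172).

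Several large gene families were bound less often than other genes. Chemoreceptor GPCR genes were bound at 10 of 1293 (0.773%, adjusted exact p = 3.15e-76), the strongest being srh-16, srh-2, sri-5 and sre-23. C-type lectins were bound at 5 of 240 (clec-87, clec-53, clec-126 and clec-104 strongest, adjusted exact p = 1.17e-10), F-box genes at 18 of 322 (fbxa-90, fbxc-19, fbxc-54 and fbxb-85, adjusted exact p = 7.39e-07) and cuticle collagens at 6 of 156 (col-38, col-2, col-71 and col-8, adjusted exact p = 5.21e-05). None of 33 hypodermis genes was bound (adjusted exact p = 0.0131), a call lost with the 1742 strongest peaks and with the narrower window (adjusted exact p = 0.210 and 0.0552), where the count stayed at 0 of 33 and the rate of other genes fell to 8.82% and 12.17%. Major sperm protein genes were bound at 1 of 53, msp-38 (adjusted exact p = 0.00663), of which 42 have promoters with under 90% unique sequence. Among those with unique promoters 0 of 11 were bound, against 16.43% of other genes, too few genes for a call (adjusted exact p = 0.290). Against genes with a pooled region, the F-box call was lost (adjusted exact p = 0.0711). Over the 39 lists, 14 were bound more often and 7 less often than other genes, with 14 and 6 in replicate 1's list and 15 and 7 in replicate 2's.

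**Figure D3:**
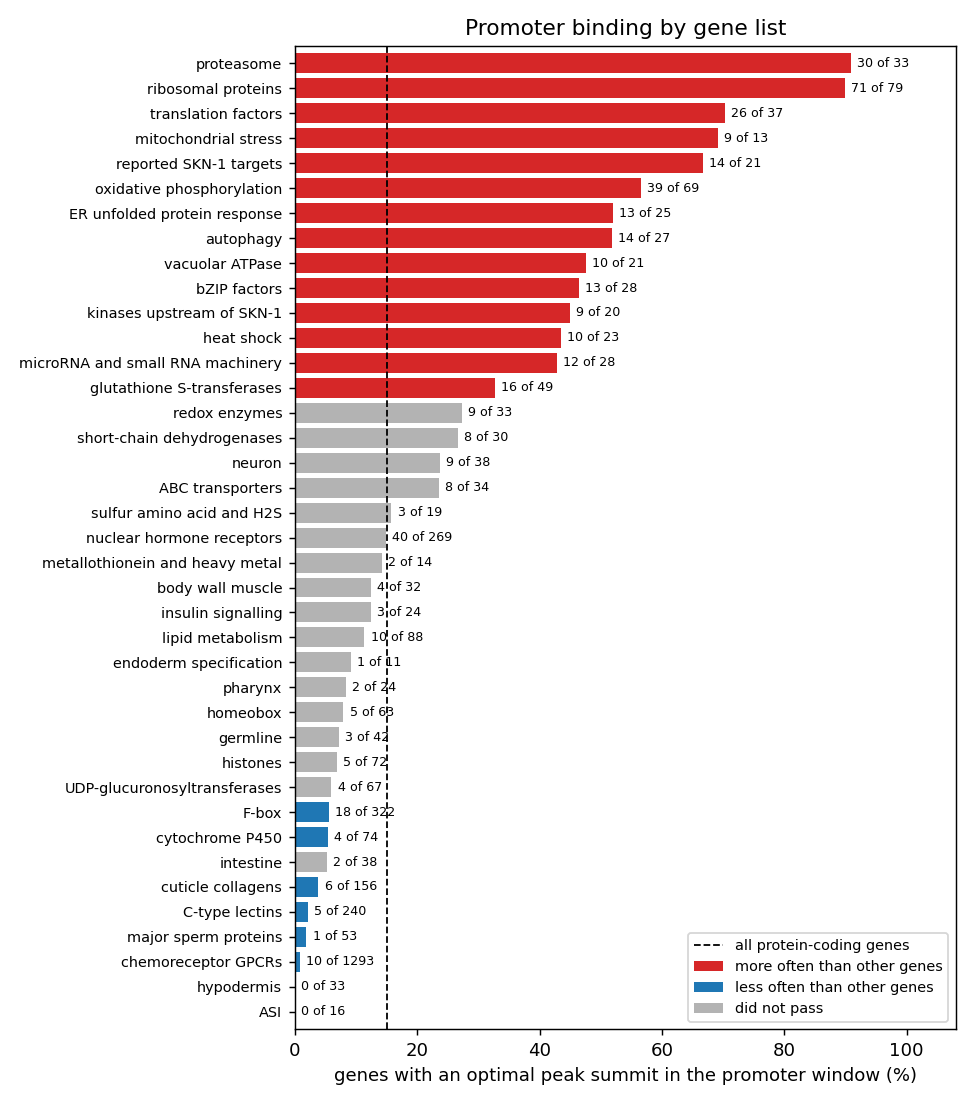
Percent of the protein-coding genes of each of the 39 lists with an optimal peak summit in the promoter window, with bound and total genes beside each bar and the 15% of all protein-coding genes as a dashed line. Colours give the outcome of Fisher's exact test with Benjamini-Hochberg adjustment; the 14 lists above the line that passed run from 32.7% to 90.9%.

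Peaks were unevenly spread over the chromosomes. The X chromosome held 682 peaks (19.6%, 18.3 to 20.9), against 14.8% of promoter bases (ratio 1.33, exact binomial p = 1.27e-14), with 20.1% in replicate 1 and 19.7% in replicate 2. Against the 17.7% of genome length on X the ratio was 1.11 (exact binomial p = 0.00361). On X as a whole the excess came from peaks outside promoters, by a split made after the data were seen. X held 324 of the 2299 promoter peaks (14.1%, against 14.8% of promoter bases, exact binomial p = 0.394) and 358 of the other 1185 (30.2%, against 18.7% of bases outside promoters, exact binomial p = 1.33e-21). The left end was the densest, where the 2.5 Mb from 0.5 to 3 Mb held 174 of the 682 peaks in 14.1% of the chromosome's length. There the excess held in promoters too, with 76 promoter peaks against 248 on the rest of X, 2.13 times as many per promoter base (exact 95% interval 1.62 to 2.76). Without that segment, alternatives added after it was seen, X held 15.3%, above the 13.1% of promoter bases (ratio 1.17, exact binomial p = 2.33e-04) but not above the 15.6% of genome length (exact binomial p = 0.755), and promoter peaks alone were below the promoter bases (11.2%, exact binomial p = 0.00519). On the autosomes, 1201 of 2802 peaks (42.9%, 41.0 to 44.7) lay in the middle of 3 equal parts of the chromosome, against 37.3% of promoter bases (exact binomial p = 2.21e-09), with 41.4% in replicate 1, 44.3% in replicate 2 and 44.1% of promoter peaks alone.

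**Figure D4:**
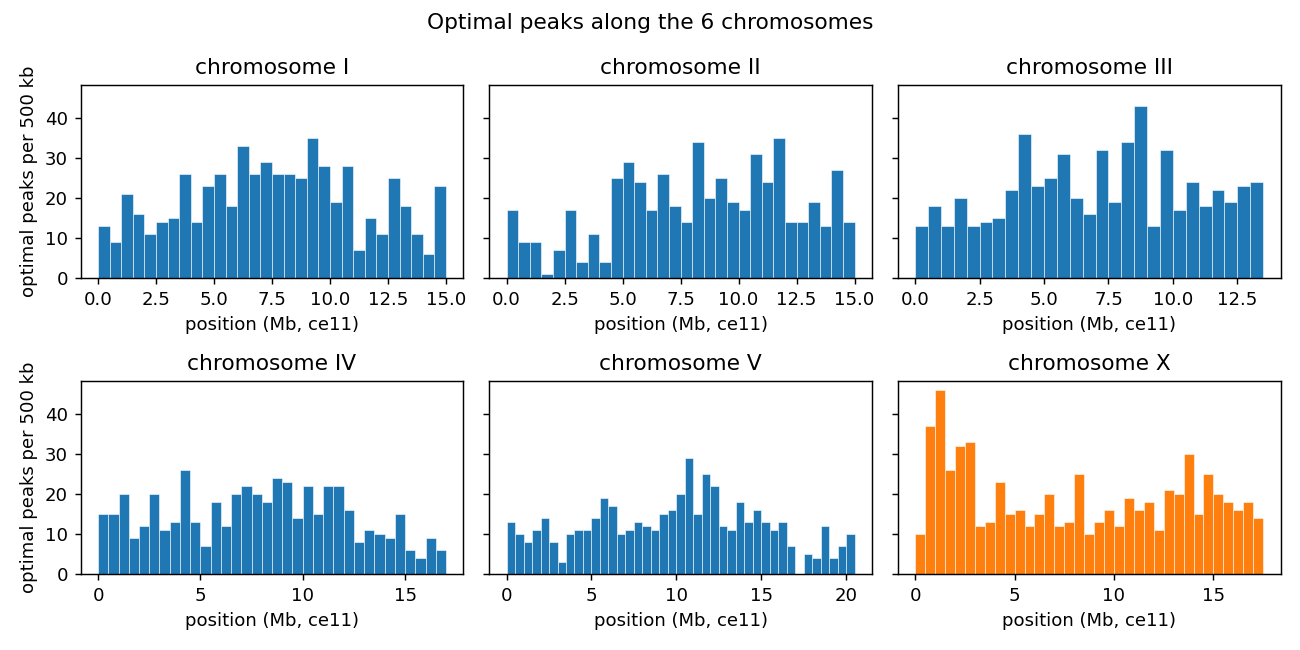
Number of optimal peaks per 500 kb window along each of the 6 chromosomes, in Mb of ce11. The highest window, on X between 1 and 1.5 Mb, held 46 peaks, against a median of 16 over all windows.

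The sequence preferred by SKN-1, WWTRTCAT, was present at a minority of summits and was most frequent at the strongest. It lay within 75 bp of 9.35% of summits and in 6.47% of control windows (325 and 225 of 3476 pairs, ratio 1.44, exact McNemar test, adjusted exact p = 1.30e-05), and its ratio exceeded those of all 500 permuted versions, whose median was 0.597. The ratio was 1.46 in replicate 2's list and 1.18 in replicate 1's, where it did not pass (adjusted exact p = 0.0527). Against promoters with no region, a control chosen after the data were seen, the ratio at promoter peaks was 1.00 (bootstrap 95% interval 0.837 to 1.2). That control does not match base composition, with 34.4% GC against 42.9% at these summits, and the ratio exceeded those of all 500 permuted versions there (median 0.559). By signal, the motif was at 14.9% (12.5 to 17.8) of the strongest of 5 bins and at 6.89% to 8.61% of the others. It was at 13 of the 20 strongest peaks (65.0%, 43.3 to 81.9) and 36 of the 100 strongest. Peaks with the motif ranked 8.12 percentile points higher on average than those without (permutation p = 1e-05, the smallest the permutations can give), with 4.95 points in replicate 1 and 7.34 in replicate 2.

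Other sequences separated summits from their surroundings more widely. GAGAGA was at 34.6% of summits and 9.61% of control windows (ratio 3.6, adjusted exact p = 1.36e-140), and CTGCGTCT, the element fixed beforehand as M8, at 12.8% and 1.01% (ratio 12.7, adjusted exact p = 1.15e-94). The M8 ratio was above 99.6% of its permuted versions and that of GAGAGA above 94.7% of the 19 it has. The forkhead site GTAAACA bound by DAF-16 (ratio 2.43), the E-box CACGTG (2.00), the AP-1 site TGASTCA (1.68) and the PHA-4 site TRTTKRY (1.09) also passed, with adjusted exact p of 6.75e-08, 1.36e-09, 0.00576 and 0.00732. Their ratios were above 99%, 80.2%, 98% and 96.9% of their permuted versions, respectively. The PHA-4 call was lost in 5 alternatives, and the AP-1 call with control windows 500 bp away (adjusted exact p = 0.104) and against promoters with no region. The GATA site TGATAA (ratio 0.603), the heat shock element TTCNNGAA (0.573), TATAAA (0.631) and runs of 8 T (0.617) were less frequent at summits, with adjusted exact p of 5.88e-13, 1.03e-10, 1.83e-12 and 2.01e-15, and TATAAA and the T run lost their call with 150 bp either side of the summit. The ratios of the first 3 were ordinary for their base composition, above 44.1%, 24% and 64.3% of their permuted versions (median ratios 0.619, 0.703 and 0.618), and the T run has no permuted version. The CRE TGACGTCA did not pass (ratio 1.52, adjusted exact p = 0.148), nor in replicate 1's list (1.21, adjusted exact p = 0.532), but passed in replicate 2's (1.82, adjusted exact p = 0.0300). Mean GC content was 43.5% at summits and 36.3% in control windows. Of 2080 6-mers, 627 were more frequent at summits at an adjusted p of 0.01 and 593 less frequent. The 10 with the largest ratios among those at 5% of peaks or more all contained CG, and were GCGCGC (ratio 11.1), ACGCGC (7.82), CGCGCG (7.63), CACGCG (6.92), ACGCAG (6.74), GCGCAC (6.32), CGCGCA (6.25), CGCGCC (6.14), AGCGCG (5.58) and GCGCCC (5.56).

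**Figure D5:**
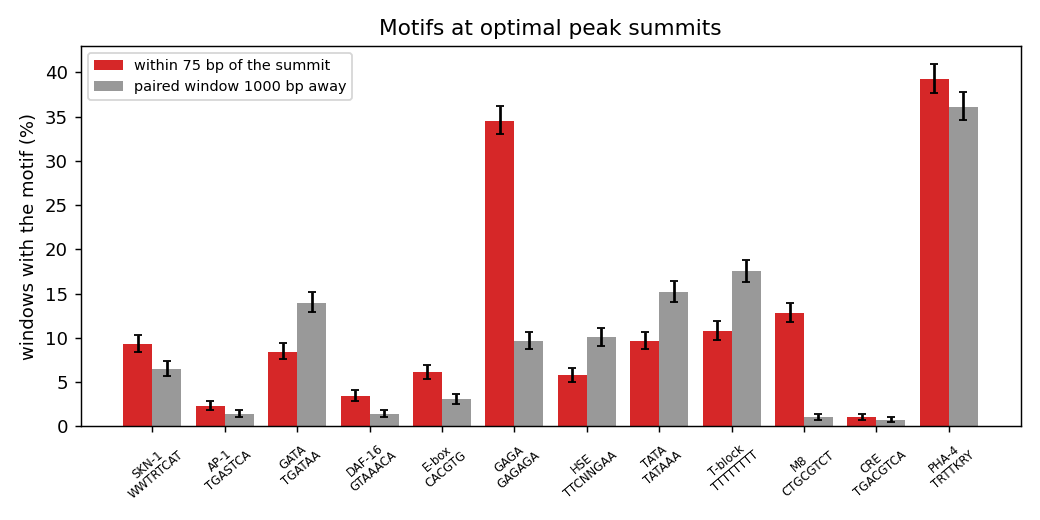
Percent of windows with each of the 12 motifs, within 75 bp of 3476 optimal summits (red) and in the paired window 1000 bp away (grey), with Wilson 95% intervals as whiskers. GAGAGA stands at 34.6% against 9.61% and CTGCGTCT at 12.8% against 1.01%, while TGATAA, TTCNNGAA, TATAAA and the T run are lower at summits.

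Peaks were also frequent near small structural RNA genes. Summits lay within 200 bp of a tRNA gene in 151 cases (4.33%, 3.71 to 5.06), 15.9 times the share of the genome so covered (exact binomial test, adjusted exact p = 9.43e-123), with ratios of 16.9 in replicate 1 and 12.9 in replicate 2. For snoRNA genes there were 80 summits (2.30% against 0.182%, adjusted exact p = 5.43e-58), for snRNA genes 13 (5.69-fold, adjusted exact p = 1.47e-06), for miRNA genes 12 (2.93-fold, adjusted exact p = 0.00140) and for lincRNA genes 29 (2.68-fold, adjusted exact p = 4.62e-06). Genes annotated as ncRNA had 486 (3.98-fold, adjusted exact p = 7.88e-144). All these folds are against the whole genome, and summits in protein-coding promoters, themselves 2.52-fold in excess, were not set apart. Summits were fewer than their share of the genome near piRNA genes (33, 0.286-fold, adjusted exact p = 1.84e-19) and pseudogenes (20, 0.143-fold, adjusted exact p = 3.38e-37), and antisense RNA genes (9 summits, adjusted exact p = 0.0722) and rRNA genes (0 summits, interval up to 0.110%) did not pass. The stretches near rRNA genes cover 0.0170% of the genome, too little for a deficit to pass. The snRNA and miRNA calls were lost when the summit had to fall inside the gene, where antisense RNA genes gained a call. The lincRNA call was lost with the 1742 strongest peaks.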

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

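Chosen after the data were seen were the random regions of replicate 2, the promoters with no region, the X share without 0.5 to 3 Mb (against promoter bases and against genome length), the X share of promoter peaks with and without it, the middle share of promoter peaks, and the gene list tests without the genes around skn-1, without those at 0.5 to 3 Mb of X and on unique promoters. The optimal peak count fell to 2271 when a summit was required among the strongest regions of both replicates, mostly by loss of weak peaks. Replicate overlap moved with its definition, to 53.5% at 50 bp, 68.9% at 200 bp, 69.8% for any overlap of regions and 68.7% for the 1742 strongest regions of each list. The 9.79% against random regions of replicate 2 is a chance level and not another value of the overlap. The ratio of the SKN-1 motif was 1.18 without replicate 2 (adjusted exact p = 0.0527) and 1.46 without replicate 1. It was 1.00 against promoters with no region (adjusted exact p = 1), which are poorer in GC. The cause was not tested for these or for the list calls below, beyond the fewer peaks or genes that some alternatives leave. The X share was not above expectation in 3 alternatives, at 14.1% of promoter peaks (14.8% expected, exact p = 0.394) and, without 0.5 to 3 Mb of X, at 11.2% of promoter peaks (13.1% expected, exact p = 0.00519) and at 15.3% against genome length (15.6% expected, exact p = 0.755). It stayed above in the others. The shares of promoters and of the middle of the autosomes and the relation of the motif to strength kept their direction and their side of 0.05 under each alternative run, with promoter shares of 55.3% to 78.1%, the extremes coming from the narrower and wider windows. Lists called numbered 17 to 24 against 21, 6-mers called 489 to 653 against 627, motifs called 8 to 12 against 11 and gene types called 7 or 8 against 8. By adjusted p, the cytochrome P450 call was 0.236 without replicate 2 and 0.0381 without replicate 1, and was lost with the 1742 strongest peaks (0.516), the narrower window (0.0572), the nearest gene (0.0947), the logistic model (0.0542) and unique promoters (0.0649). Its odds ratio was 0.591 with the 1742 strongest peaks and 0.536 without replicate 2, but 0.305, 0.375 and 0.356 with the narrower window, the nearest gene and unique promoters, against 0.322. Redox enzymes, at 0.274 without replicate 2 and 0.0414 without replicate 1, were also called more often bound with the 1742 strongest peaks (0.0489) and the logistic model (0.0329). With the 1742 strongest peaks, kinases (0.0546), hypodermis (0.210, still 0 of 33) and major sperm proteins (0.169) lost their call. With the narrower window, kinases (0.146) and hypodermis (0.0552) lost it and short-chain dehydrogenases gained one as more often bound (0.0483). With the wider window UDP-glucuronosyltransferases (0.00876), intestine genes (0.0379) and histones (0.0271) gained one, all as less often bound. Against the 8920 genes with a pooled region, a smaller background, glutathione S-transferases (0.101), kinases (0.0993), small RNA machinery (0.123), F-box genes (0.0711) and major sperm proteins (0.707) lost their call. There UDP-glucuronosyltransferases gained one as less often bound (0.0294). Among unique promoters, major sperm proteins lost their call (0.290, 0 of 11) and UDP-glucuronosyltransferases gained one as less often bound (0.0134). Histone genes were called less often bound than other genes with the nearest gene (0.0421) and the logistic model (2.08e-04), but more often among unique promoters (5 of 9, adjusted exact p = 0.0172). In total, the 21 lists called kept their call in 214 of 231 cases and lost it in 17, and the other lists stayed without one in 186 of 198, gained one in 11 and turned in 1, that of histone genes. Of the 137 named genes that were bound, 134 were also bound in replicate 2's own list and 127 in replicate 1's. With the 1742 strongest peaks 117 were, and with the wider window 137. The narrower window kept 116, with gcs-1, ikke-1, rict-1 and hsp-60 among those lost. The nearest gene kept 107, with gst-4, hsp-6, hsp-60, eef-1A.1, rpl-20, rict-1, mut-15 and rde-8 among those lost. The number of reads and of control reads, which set how weak a site could be detected, is not known here.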

Other observations

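Tests chosen only after the result was seen were the per-list motif comparison, with and without the peaks of reported targets, the gap percentile and the promoter share of the gap for skn-1, and the promoter-base comparison on X. The SKN-1 motif was unevenly spread over the bound gene groups. It lay within 75 bp of the strongest promoter peak for 14 of 14 peaks at reported SKN-1 targets (adjusted p = 1.87e-14, two-sided Fisher's exact test against other promoter peaks, 25 lists), 11 of 15 at glutathione S-transferases (1.76e-08), 14 of 30 at proteasome genes (2.61e-07) and 6 of 9 at redox enzymes (1.55e-04), against 8.57% of all 2299 promoter peaks. None of 39 peaks at oxidative phosphorylation genes, 14 at autophagy genes, 10 at heat shock genes or 9 at mitochondrial stress genes had it, and none of these 4 differences passed (adjusted exact p = 0.240 to 1). The list of reported targets was drawn up from earlier work, in which such sites can have helped to define targets, and 6 of the glutathione S-transferase peaks and 3 of the redox peaks, all with the motif, are also theirs. Without the peaks of reported targets, 5 of 9 glutathione S-transferase peaks (adjusted exact p = 0.00362) and 14 of 30 proteasome peaks (3.08e-07) had the motif, while 3 of 6 redox peaks did not pass (0.0675). None of these comparisons was matched for peak strength, which the motif followed. Of the 30 bound proteasome genes, 29 had their peak in the strongest of the 5 bins by signal. The motif was at 14.9% of all peaks in that bin and at 36 of the 100 strongest.

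It was hypothesised before this test was run that the motif would be more frequent at proteasome than at ribosomal protein promoters. That both were bound at similar rates is itself a result of these data. The motif was at 14 of 30 proteasome peaks and 1 of 68 ribosomal protein peaks (odds ratio 58.6, two-sided Fisher's exact p = 5.50e-08). The 2 groups were not matched for peak strength, with median ranks of 65 for proteasome and 466 for ribosomal protein genes. A second hypothesis, that the motif would lie closer to the summit at the 696 strongest peaks, was neither shown nor excluded. The mean distance was 31.9 bp (SD 17.2) there and 33.3 bp (SD 20.4) at the others, over 327 peaks with the motif (two-sided permutation p = 0.560).

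The first pattern weighed was the absence of regions around skn-1. The gap between neighbouring summits there was at percentile 99.9867 of all gaps in replicate 1's full list and 99.9833 in replicate 2's. Repeated sequence is argued against, since 96.9% of the 30-base words in the gap occur once in the genome, against a 5th percentile of 75.2% for windows of that length and 6.85% in the longest gap, 233375 bp on chromosome V around gst-10. Fewer promoter bases is argued against too, since promoters other than those of chemoreceptor genes cover 26.3% of the gap, against a 5th percentile of 12.07% for such windows. The 0.374% of 8556 windows with a like promoter share that held no pooled region decides nothing, since only 0.465% of all such windows are empty. A remaining candidate explanation, that copies of the locus in the transgene raised the shared control's reads there, cannot be told apart from other causes because the strain of the control is not given and its alignment was not analysed here, and no biological explanation was tested.

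The second pattern was the excess of peaks at the left end of X. More promoter bases there is argued against as the whole cause, since promoter peaks per promoter base were 2.13 times as dense as on the rest of X (exact 95% interval 1.62 to 2.76). Extra copies of the whole segment in the worms, relative to a control whose strain is not given, predicted that regions in coding sequence, where few optimal peaks lie, would be denser too. In the full lists, such regions were 2.19 (1.76 to 2.69) times as dense in replicate 2 and 2.29 (1.90 to 2.74) in replicate 1. However, the segment was picked from these data for its density. Intron (1.76 and 1.88), intergenic (1.70 and 1.80) and promoter regions (1.62 and 1.68) were denser in replicates 2 and 1 as well. The test therefore cannot tell extra copies, which remain a candidate, from other causes of a dense segment. A biological explanation was not tested, and 5 of the 20 strongest peaks lie in the segment, against 0 on the rest of X.

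The third pattern was GAGA and GC-rich sequence at the summits. Promoter composition common to unbound genes is argued against as the whole cause, since GAGAGA was 3.95 (bootstrap 95% interval 3.43 to 4.61) times as frequent at promoter summits as at the same distance from the start of genes with no region. Base composition alone is argued against for M8, whose ratio exceeded 99.6% of its permuted versions. For GAGAGA it is not settled. Against paired control windows its ratio of 3.6 exceeded 94.7% of its 19 permuted versions, the highest at 3.95. Against genes with no region it exceeded all 19, the highest at 3.72, but those windows hold 34.4% GC against 42.9% at the summits. What these sequences mark stays open, since a list of sites bound by other factors in L1 larvae was not used here, and no biological explanation was tested.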
